A study of Mus musculus with 6 samples.

How the data were processed

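Total RNA from heart tissue of wild-type mice was sequenced in 6 libraries, 3 from sham-operated mice and 3 from mice with chronic kidney disease after subtotal nephrectomy. Per the labels all 6 carry 1 batch label, so no batch term was needed. Per the submitters' processing notes, Trimmomatic, HISAT2, HTSeq and DESeq were used with the mouse build mm9, and versions, settings, strandedness and the annotation are not given in the sources used here. The deposited values are raw counts per gene symbol, as whole numbers in a single table with 1 column per heart, and columns were matched to hearts by name. The labels do not say beyond the replicate numbers that the samples are separate animals, so p-values measure the spread between these samples.

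The column totals were 10480788, 10474487 and 12669724 counts in sham and 11717426, 11989540 and 12222637 in CKD. A gene at 0 counts in a column is allowed up to 3 counts, which is 0.237 to 0.286 CPM in the sham columns, for counting error only. The table had 17447 rows, of which 87 were at 0 in all columns. Of the symbols, 17332 were found in the RefSeq gene table of assembly GRCm38.p6 and 16856 in a GENCODE gene table. These tables were used for names and for trial row orders only, and no coordinates are given because the named build is another one. Genes with near-identical copies, such as ribosomal protein, Gapdh and haemoglobin genes, are uncertain in level because the counting of shared reads is not known. Of 13 listed mitochondrial-encoded genes, 0 were found in the table under the symbols used, so they were not analysed here. CPM values and shares of counts are therefore those of a table without these rows.

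Before the planned comparison was interpreted, the row labels were checked against the values. Spearman correlations were computed between all columns, and the percentile of fixed gene lists in each group was set against 10000 random row sets of the same size. The rank correlation between groups in blocks of 600 rows was between -0.169 and 0.106. The median log2 ratio of CKD 3 to CKD 1 ran from 0.618 to -0.236 between such blocks, against 0.104 to -0.0541 for sham 3 to sham 1. It followed the alphabetical row order, rising from 0.0862 in rows 1 to 600 to 0.618 in rows 1801 to 2400. It was 0.116 in the next block and mostly fell from there to -0.236 in rows 14401 to 15000. The last block with a value was at -0.0581. The sham ratio did not follow the row order in this way. The CKD columns were then compared with the sham profile under 8 row orders that do not use the values, such as the alphabet, gene numbers and position in the genome. Each of 4 windows of 400 CKD rows was slid along the ordered sham profile, and the position with the highest Pearson r was kept. The highest r over all orders was 0.474, where sham 1 against the other sham hearts gave 0.985 to 0.988. Because it is a maximum over all positions, with no chance level computed, 0.474 is not a match at corresponding rows. No order brought the CKD columns as close to the sham profile as a sham heart. Reassigning labels by the values themselves was rejected as circular, since it would force the CKD columns to resemble sham. The gene labels of the CKD columns were therefore treated as unknown, and the fit of CKD against sham is reported as a description of the table.

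The planned fit used edgeR 4.0.16 in R 4.3.3 with filterByExpr, TMM normalization, robust dispersion estimation and the quasi-likelihood F test, with group as the sole term. Benjamini-Hochberg adjustment over all tested rows was used with a threshold of 0.05. Fold changes are CKD over sham. A set of 40 gene lists covering pathways and cell type markers was fixed before the data were examined, as were the main test and most alternatives. Of these, 38 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with camera at an estimated correlation and fry as alternatives. Rows to be named were set by a rule. It took a few fixed rows, of which 8 are given and the rest is not reported here, and the 10 largest rises and 10 largest falls among rows at adjusted p under 0.05 and at least 1 CPM on average, whose groups did not overlap and whose symbols were not predicted-gene or clone names. It also took up to 3 members of each list with the smallest p. Sham genes beyond that rule were picked from the fixed lists to describe the sham hearts, in part after their values were seen.

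To see what detached labels would give, the rows of the CKD block were shuffled 20 times with the 3 columns kept together. Every split of the 6 columns into 3 and 3, of which there are 10, was also fitted. Group measures that need no label were compared with an exact two-sided permutation test in scipy 1.17.1, for the columns as deposited and thinned to 10474487 counts. Levels in sham hearts were computed as CPM from the deposited counts and the column totals.

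The scripts were tested on simulated counts for 12014 genes with means and library sizes from these data, of which 200 were changed. The edgeR test called 144 genes, of which 8.33% were false, and recovered 22% of genes changed 1.5-fold, 70% of those changed 2-fold, 100% of those changed 4-fold and 72% of those lowered to 0.5-fold. After the rows of 3 simulated libraries were shuffled, 85.9% of the genes were called. Alternatives were DESeq2 1.42.0, limma voom, the legacy quasi-likelihood method, other size factors, other filters, fold minimums, the replicate number as a block, and leaving out each heart in turn. Other software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.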

Results

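RNA was sequenced from 6 heart samples of wild-type mice, 3 from sham-operated mice and 3 from mice with chronic kidney disease (CKD) produced by surgical removal of most of the kidney tissue. The table held counts for 17447 gene symbols, and the totals were 10480788, 10474487 and 12669724 counts in the sham columns and 11717426, 11989540 and 12222637 in the CKD columns. Under the same gene labels, the values of the 3 CKD columns did not correspond to those of the 3 sham columns. For that reason the CKD labels were not relied on. Gene levels are therefore described in the sham hearts alone, and the test of CKD against sham is given as a property of the table and not as a set of gene changes. Each level is a mean in CPM, the count scaled to the total of its column, with its SD over 3 sham hearts.

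The first question was which genes differ between CKD and sham hearts. In the sham columns the row labelled Myh6, the main adult myosin heavy chain of the mouse heart, held 362529, 443278 and 474768 counts, and in the CKD columns it held 0, 0 and 1. The row of Mb, which encodes myoglobin, held 146576, 148130 and 160714 counts in sham and 0 in each CKD column. The ventricular light chain Myl2 held 123803, 113232 and 133851 counts in sham and 0, 0 and 1 in CKD. Atp2a2, the sarcoplasmic reticulum calcium pump, held 197028, 229827 and 247428 counts in sham and 85, 92 and 127 in CKD. The highest CKD row was labelled Eqtn, a sperm acrosome gene, with 399006, 475298 and 459605 counts in CKD and 2, 1 and 2 in sham. Sp6, a transcription factor of tooth and skin development, followed among the highest with 202925, 200370 and 226890 counts in CKD and 2, 4 and 4 in sham. The 56 rows labelled as olfactory or vomeronasal receptors had a median of 0 counts per sham heart and 25 per CKD column, and 18 of them averaged at least 100 counts in CKD against 1 in sham.

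**Figure D1:**
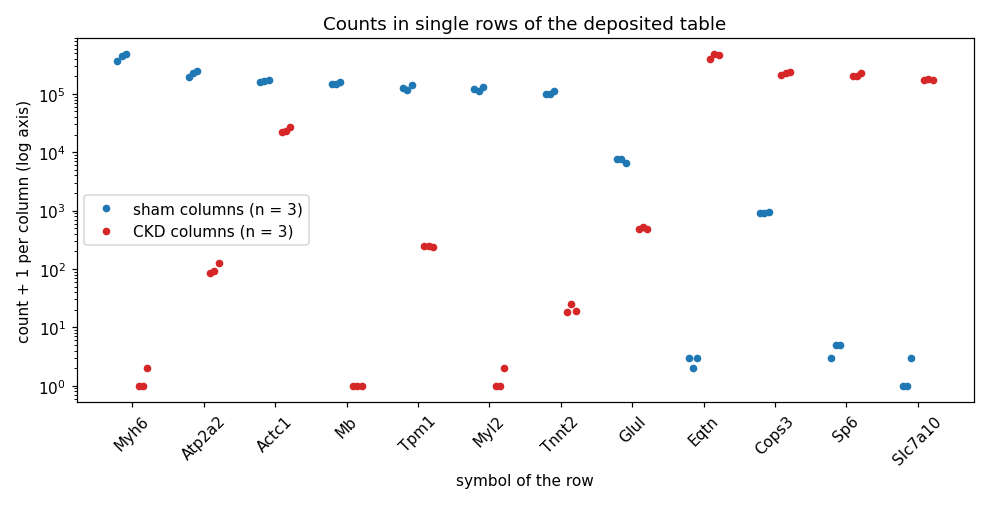
Counts plus 1 on a log axis for single rows of the table, with each point 1 column, blue for the 3 sham columns and red for the 3 CKD columns. The heart muscle rows Myh6, Mb and Myl2 held at least 113232 counts in every sham column and held at most 1 in any CKD column, while Eqtn held at most 2 counts in sham and at least 399006 in CKD.

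Across all rows, the Spearman correlation was 0.982 to 0.985 for the 3 pairs of sham columns and 0.984 to 0.987 for the 3 pairs of CKD columns. For the 9 pairs of a sham with a CKD column it was -0.0586 to -0.0528. These are correlations across genes, which are not independent replicates. Sorted from lowest to highest without regard to label, the log2 mean CPM values of both groups gave a Pearson r of 0.9999. Sorting leaves only the 2 distributions to compare, and no unrelated library was set beside them. This r therefore does not show that the CKD columns hold the same values in another order. The 72 nuclear-encoded oxidative phosphorylation rows had a median percentile of 98.5 among all sham rows and 58.1 among all CKD rows, where random sets of 72 rows gave 38.9 to 61.2 (central 95%). The 15 ventricular cardiomyocyte marker rows stood at a median percentile of 99.9 in sham and 44.6 in CKD, with 26.5 to 73.5 for random sets. The 25 contraction and calcium handling rows stood at 99.9 and 40.4, with 31.8 to 68.3 for random sets. The 78 cytoplasmic ribosomal protein rows stood at 95.3 and 21.1, below the 39.2 to 60.7 of random sets, and most of their symbols are neighbours in the alphabetical table. In the last 900 rows, 897 were at 0 in every CKD column and 36 in every sham column.

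**Figure D2:**
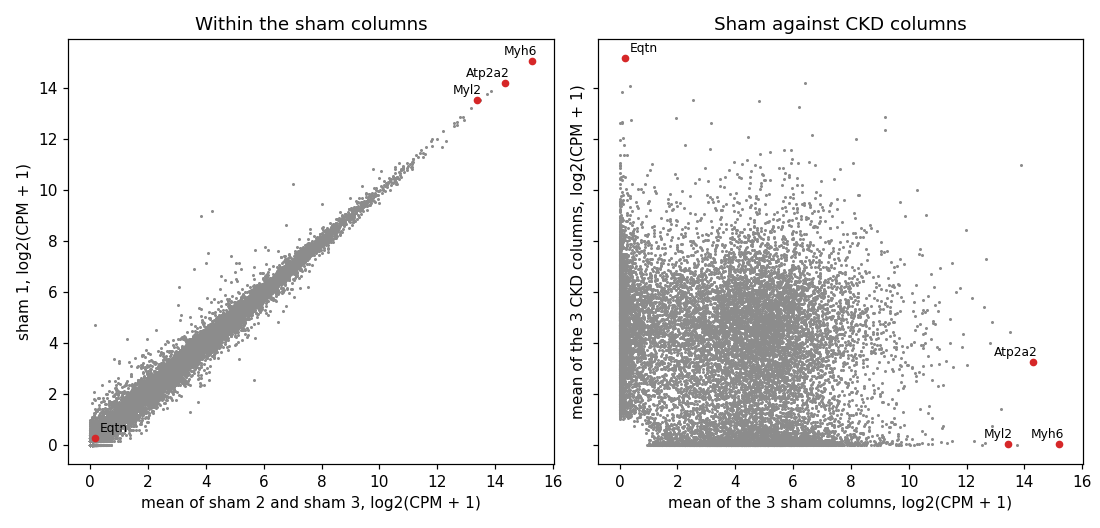
Each point is 1 of the 16085 rows tested, as log2(CPM + 1), for sham 1 against the mean of the other sham columns (left) and for the mean of the 3 CKD columns against the mean of the 3 sham columns (right). The rows lie along the diagonal within sham and spread over the whole plane between the groups. Over all 17447 rows, tested or not, pairs of sham columns had a Spearman correlation of at least 0.982. No pair of a sham with a CKD column exceeded -0.0528.

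Fitted as planned, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 14918 of 16085 tested rows (92.7%) differed at an adjusted p under 0.05, with 7374 higher and 7544 lower in CKD. With the rows of the CKD block put in random order, its 3 columns kept together, 14612 to 14729 rows were called in 20 shuffles, which was 92.39% to 92.98% of the rows tested. Because the labels of the CKD columns could not be relied on, no such difference is read as a change of a gene in CKD hearts.

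The rows fixed for naming that are reported here were all lower in the CKD columns by the same edgeR test. All were high in sham, from percentile 92.2 for Rcan1 to 100 for Myh6. Unrelated CKD values would also be mostly lower there, so the direction says nothing about CKD. Nppa and Nppb, which encode natriuretic peptides, had adjusted p = 0.0112 and 1.68e-06, with log2 differences of -5.77 (SE 1.37) and -2.51 (SE 0.218). The Nppa difference was -4.10 without sham 1, and its call was lost with limma voom (adjusted p = 0.0822). The rows of the skeletal actin Acta1 and the calcineurin regulator Rcan1 were at -1.66 (adjusted p = 0.00475) and -0.55 (adjusted p = 0.0474), and the call of Rcan1 was lost in 8 of 16 alternatives, including the replicate block (adjusted p = 0.0858). The collagen row Col1a1 was at -6.93 (adjusted p = 0.0007), and at -6.34 without sham 3. Myh7, the slow myosin heavy chain raised in many forms of hypertrophy, held 4141, 639 and 2445 counts in sham and 0 in each CKD column. By the fixed rule, the rows with the largest fall included Myl3 (a myosin light chain), Slc25a4 (the mitochondrial ADP/ATP carrier) and Sdhb (a complex II subunit). Slc25a4 held 62565, 73109 and 77860 counts in sham and 1, 0 and 1 in CKD. The rows with the largest rise included Lin28a, an embryonic RNA-binding protein, Hoxa9, a homeobox gene, and Gapdhs, a sperm glycolytic enzyme. Lin28a held 0 counts in each sham column and 78170, 78682 and 70233 in the CKD columns.

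Gene lists behaved in the same way. With camera at a preset correlation, 20 of 38 lists were called, 4 higher and 16 lower, and shuffled tables gave 17 to 25. With an estimated correlation camera called 0, with 7 at an unadjusted p under 0.05, and fry called 35. Of 34 tested rows of the glutamine and amino acid metabolism list, 10 were higher and 22 lower (32 adjusted over the list alone). That list had a camera adjusted p = 0.185, and adjusted p = 0.387 with an estimated correlation. Of the 72 oxidative phosphorylation rows, 2 were higher and 68 lower (70 adjusted over the list alone), with a camera adjusted p = 1.62e-10 and adjusted p = 0.102 with an estimated correlation. All 24 tested contraction and calcium handling rows were lower (24 adjusted over the list alone), with a camera adjusted p = 4.47e-07 and adjusted p = 0.102 with an estimated correlation. Of the 78 ribosomal protein rows, 2 were higher and 73 lower (75 adjusted over the list alone), with a camera adjusted p = 9.17e-11 and adjusted p = 0.218 with an estimated correlation. The oxidative phosphorylation, contraction and ribosomal protein rows had median percentiles of 98.5, 99.9 and 95.3 in sham. Unrelated CKD values set beside rows so high would also be mostly lower, so this direction says nothing about CKD. These counts describe which labels stood beside which CKD values.

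Measures that need no row label could be compared between the groups. Rows with at least 1 count numbered 14894 ± 334 in sham and 14810 ± 74.0 in CKD columns (SD, n = 3 each; exact two-sided permutation p = 0.7). Rows with at least 10 counts numbered 12597 ± 321 and 12530 ± 76.6 (exact permutation p = 0.8). The highest row took 3.81% ± 0.391 of the counts in sham and 3.71% ± 0.283 in CKD (exact permutation p = 0.8). The 10 highest rows took 14.1% ± 0.760 and 14.3% ± 0.364 (exact permutation p = 0.7), and the 100 highest 32.9% ± 1.49 and 33.6% ± 0.580 (exact permutation p = 0.5). The Benjamini-Hochberg adjusted p was 0.8 for each of these 5 measures, and 3 hearts against 3 cannot give a p below 0.1.

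In the sham hearts, the labels fitted the values. Genes of contraction and calcium handling led the profile and took 15.1% ± 0.854 of all counts, with all 25 measured members at 1 CPM or more. Myh6 was the highest gene at 38130 ± 3910 CPM, followed by Atp2a2 at 20090 ± 1640 and the cardiac actin Actc1 at 15010 ± 1220. Mb stood at 13600 ± 800 CPM, tropomyosin Tpm1 at 11570 ± 363, Myl2 at 11060 ± 661 and the troponin Tnnt2 at 9329 ± 417. In all, 12491 genes averaged at least 1 CPM and 104 at least 1000 CPM. Over the 8864 genes with at least 10 CPM, the median coefficient of variation between the 3 sham hearts was 9.32%.

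Mitochondrial energy genes formed the next large block. Nuclear-encoded oxidative phosphorylation genes took 5.45% ± 0.169 of the counts, and all 72 exceeded 100 CPM. Atp5b, the catalytic beta subunit of ATP synthase, reached 7179 ± 274 CPM. The tricarboxylic acid cycle and pyruvate oxidation list took 2.88% ± 0.184, with Ogdh (2-oxoglutarate dehydrogenase) at 4069 ± 319 CPM, Idh2 at 2523 ± 177 and citrate synthase Cs at 2189 ± 206. Fatty acid uptake and oxidation took 3.21% ± 0.342, and 30 of its 36 genes exceeded 100 CPM. Lpl, the lipoprotein lipase, stood at 7479 ± 723 CPM, the fatty acid binding protein Fabp3 at 4147 ± 746, the transporter Cd36 at 1923 ± 126 and Cpt1b, the muscle carnitine palmitoyltransferase, at 850 ± 103. Glycolysis and glucose uptake took 1.87% ± 0.0945, with Aldoa at 3658 ± 382 CPM and the lactate dehydrogenase subunits Ldhb at 2090 ± 31.5 and Ldha at 747 ± 39.7. The insulin-responsive glucose transporter Slc2a4 was at 583 ± 74.8 CPM and Slc2a1 at 19.9 ± 5.45. Genes of branched-chain amino acid and ketone oxidation took 0.555% ± 0.0215, with Oxct1, the enzyme that activates ketone bodies for oxidation, at 1783 ± 118 CPM.

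Glutamine and amino acid metabolism took 0.491% ± 0.0456 of sham counts, and 33 of its 34 genes averaged at least 1 CPM. The aspartate aminotransferases were its highest members, with Got2 at 1360 ± 90.1 CPM and Got1 at 1342 ± 249. Glul, the glutamine synthetase, stood at 666 ± 134 CPM and Glud1, the glutamate dehydrogenase, at 198 ± 6.94. Among the glutamine carriers, Slc38a2 was at 210 ± 23.1 CPM, Slc1a5 at 24.1 ± 3.09 and Slc38a1 at 18.1 ± 6.89.

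Receptors and carriers linked to phosphate, FGF23 and angiotensin were also read in sham hearts. The sodium-phosphate carrier Slc20a2 was at 224 ± 3.94 CPM and the related Slc20a1 at 17.9 ± 3.49. The angiotensin receptor Agtr1a was at 61.2 ± 3.00 CPM and Fgfr1 at 50.5 ± 11.2. Fgfr4 gave 3, 1 and 3 counts and Kl, the FGF23 co-receptor, 0, 0 and 2. Fgf23 gave 0 counts in each sham heart, which allows up to 0.286 CPM in the shallowest column, for counting error only.

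Of 17 hypertrophy and fetal programme genes with at least 1 CPM, 10 had a coefficient of variation of 30% or more among the sham hearts, while Xirp1 at 329 ± 24.3 CPM and Myocd at 99.6 ± 7.43 varied little. Nppa gave 12772, 675 and 3186 counts in sham 1, 2 and 3, a mean of 512 ± 619 CPM that fell to 158 without sham 1. Myh7 gave 4141, 639 and 2445 counts and a mean of 216 ± 168 CPM, which was 127 without sham 1. Acta1 was at 578 ± 269 CPM and Ankrd1, a stretch-responsive gene of muscle, gave 18210, 7902 and 18931 counts. Nppb was steadier at 125 ± 38.0 CPM. Of 13 atrial markers with at least 1 CPM, Nppa included, 11 were highest in sham 1, while Kcnk3 was highest in sham 2 and Gja5 in sham 3. Without Nppa, the atrial list took 0.210% of the counts in sham 1, 0.0579% in sham 2 and 0.0787% in sham 3. Myl7, the atrial regulatory light chain, gave 5207, 15 and 1032 counts, and the atrial calcium pump regulator Sln gave 1152, 2 and 205.

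Extracellular matrix genes took 0.510% ± 0.199 of the counts and all 40 were lowest in sham 2. Col1a1 gave 1803, 530 and 3364 counts, Col3a1 3288, 923 and 5242, and Postn, a matrix protein of activated fibroblasts, 1115, 294 and 1476. Their share was 0.567% in sham 1, 0.289% in sham 2 and 0.674% in sham 3. Among cell type markers, 14 of 15 fibroblast, 11 of 16 endothelial and 9 of 13 pericyte and smooth muscle markers were also lowest in sham 2, and the fibroblast list shares 5 genes with the matrix list (Col1a1, Col1a2, Dcn, Lum and Mfap5). The fibroblast share was 0.444% in sham 1, 0.280% in sham 2 and 0.483% in sham 3. Endothelial genes had a median coefficient of variation of 14.9% over 16 genes, with Pecam1 at 245 ± 21.9 CPM and Cdh5 at 318 ± 21.3. Cldn5 (28.3 ± 21.9 CPM), Ly6a (148 ± 61.6) and Vwf (80.1 ± 24.3) were the 3 of them at 30% or more. The macrophage gene Lyz2 was at 230 ± 55.4 CPM. Of 13 measured lymphocyte markers 2 averaged at least 1 CPM, and of 8 lung and airway markers 0 did.

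All 28 measured interferon response genes were highest in sham 3, with 0.218% of the counts against 0.0503% in sham 1 and 0.0334% in sham 2. Irf7, a transcription factor of the interferon pathway, gave 180, 137 and 2390 counts and Ifit3 gave 159, 100 and 1447. All 20 macrophage and monocyte markers were also highest in sham 3, with 0.145% of the counts against 0.103% in sham 1 and 0.0751% in sham 2. The 7 erythroid and blood genes with at least 1 CPM were also highest in sham 3, with 709, 522 and 3773 counts for Hbb-bs. Of 25 immediate early genes, 21 were highest in sham 1, 2 in sham 2 (Ier3 and Jun) and 2 in sham 3 (Fos and Socs3), with 2250, 716 and 786 counts for the phosphatase Dusp1 and 1442, 268 and 111 for the nuclear receptor Nr4a1. These are values of single hearts, and no test within the sham group was made.

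**Figure D3:**
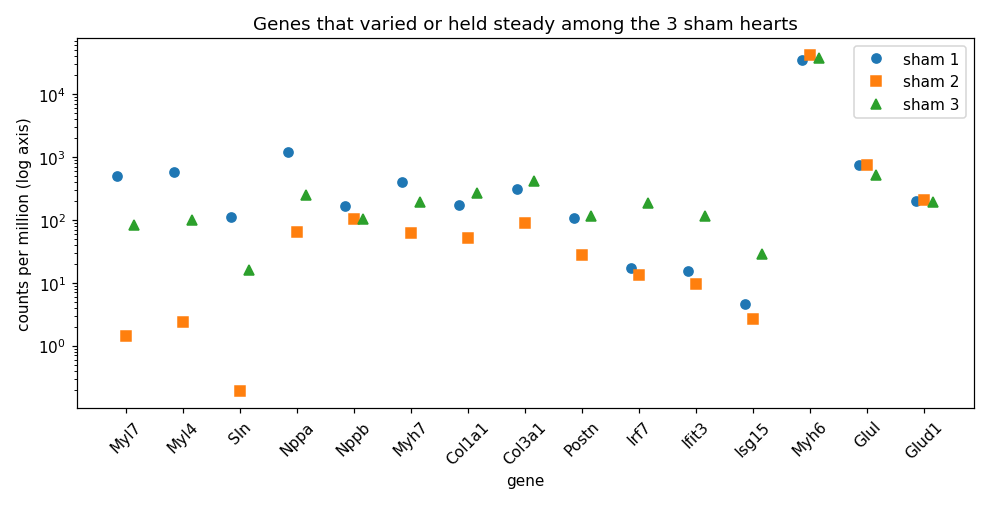
CPM on a log axis of single genes in the 3 sham hearts, with 1 point per heart. The atrial genes Myl7, Myl4 and Sln were lowest in sham 2, the interferon genes Irf7 and Ifit3 were highest in sham 3, and Myh6, Glul and Glud1 varied little by comparison.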

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

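Shuffling the CKD rows, thinning, and the alternatives for sham levels and for measures without labels were chosen after the data had been seen. The number of called rows was 13722 to 15477 over the 17 alternatives chosen before the data were examined. This stability does not bear on whether the CKD labels are right, since each alternative kept the same labels. With the replicate block 14828 rows and 20 lists were called. Whether the replicate numbers pair the samples could not be checked row by row, because the sham and CKD columns were nearly uncorrelated across rows. Lists called by camera fell from 20 to 0 with an estimated correlation and rose to 35 with fry. The cause was not tested. Of 128 alternatives for the 8 fixed rows, 10 lost the call: 8 for Rcan1 (among them the replicate block, adjusted p = 0.0858, limma voom, adjusted p = 0.127, and 5 of 6 leave-one-out fits, with adjusted p from 0.000258 to 0.16 over its alternatives), 1 for Nppa (limma voom, adjusted p = 0.0822) and 1 for Myh7 (without sham 3, adjusted p = 0.0632).

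With TMM among the sham hearts, 16 sham levels moved by less than 1 SD. Leaving out 1 of 3 hearts cannot move a mean by 1 SD, so such settings say nothing about stability, and Nppa fell from 512 to 158 CPM and Myh7 from 216 to 127 CPM without sham 1. Of 35 alternatives for the measures without labels, 7 changed sign, all when 1 heart was left out, and none of these differences had passed a test. Over the leave-one-out settings the CKD minus sham difference was -276.5 to 25.5 for rows with at least 1 count and -242.8 to 71.7 for rows with at least 10. It was -0.280 to 0.107 percentage points for the highest row and -0.105 to 0.593 for the 10 highest rows. Depth was similar in all columns, and a gene at 0 in a sham column could reach 0.286 CPM unseen.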

Other observations

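The test of a heart response to nephrectomy was chosen after the CKD rows had been seen, and the genes named next were picked after their values were seen. Of 20 clock genes, 12 were highest in sham 2, 5 in sham 1 and 3 in sham 3. Sham 2 differed most in some of them, with 52, 271 and 69 counts for Per2 and 335, 82 and 284 for Arntl in sham 1, 2 and 3, and Nr1d1, a repressor of Arntl, gave 1473, 572 and 2234, while Cry1 gave 152, 158 and 138 and Per1, lowest in sham 3, 664, 605 and 244. Low counts in sham 2 were also seen for 4 picked matrix genes, with 152, 0 and 433 counts for Chad, 133, 0 and 371 for Clec3a, 344, 1 and 736 for Fmod and 342, 4 and 689 for Comp. Of 6 mesothelial and epicardial genes with at least 1 CPM, 5 were lowest in sham 2, with 92, 1 and 34 counts for Upk3b and 46, 1 and 23 for Msln, but Wt1 was close among the hearts (62, 47 and 68) and Tbx18 was lowest in sham 3 (79, 69 and 41). The interferon-inducible GTPase genes Igtp (288, 190 and 5440 counts), Iigp1 (759, 494 and 9157) and Irgm2 (448, 308 and 4951) were among the most variable genes of the sham hearts, all highest in sham 3.

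The first pattern is that 92.7% of tested rows differed between the CKD and sham columns. Detached row labels may account for it, but the shuffling test did not decide it. The deposited table gave 101.7% of the median number of called rows in 20 tables with shuffled CKD rows. That had to be close because the groups were already nearly uncorrelated. The pairing was not quite random. Spearman correlations were -0.0586 to -0.0528 for pairs of a sham with a CKD column. They were -0.0149 to 0.0108 for the group sums in the shuffled tables. The row order adds evidence, with no condition set beforehand. Symbols stood in alphabetical order. Of rows 1 to 600, 587 averaged at least 10 CKD counts. This held for 2 of rows 9001 to 9600 and 0 of rows 16801 to 17400. In the last 900 rows, 897 were at 0 in every CKD column and 36 in every sham column. With right labels, neither another tissue nor a response to nephrectomy would empty such stretches of the alphabet. These counts argue against either as the whole cause, for the rows they cover. Detached labels stay open. The tests made for libraries from another tissue and for a heart response to nephrectomy decided nothing further, because both read the CKD values by their labels. Which tissue or response the CKD values hold, once the labels are set aside, is unknown. The ribosomal protein rows, abundant in every tissue, had a median CKD percentile of 21.1, below the 39.2 to 60.7 of random rows. That value met neither condition set beforehand for another tissue. The ventricular marker rows stood at 44.6, inside the 26.5 to 73.5 of random rows. Only with right labels would these values argue against either cause. The real split gave 14918 called rows and the highest other split 0 (edgeR, 3 to 30 at an unadjusted p under 0.05), in 1 of 10 splits; for lists, 10 of 10 splits gave as many as the real 20, with 27 as the highest other, and 10 splits are too few for a share under 0.05.

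The second pattern is the spread of Nppa, with a log2 ratio of 4.24 from sham 1 to sham 2. A share of atrial tissue in the sample is a candidate explanation: 12 other atrial markers had a median log2 ratio of 1.56 (interquartile range 0.58 to 7.21), and 11 of them were higher in sham 1. Kcnk3 was the exception. The median met the condition set beforehand for atrial tissue, which does not show how the hearts were dissected. Beyond that check no explanation was tested, since the design gives none within the sham group.

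The third pattern is the interferon genes in sham 3, first seen in Ddx58, which had a log2 ratio of 1.65 to the mean of the other sham hearts. The other 27 interferon genes had a median log2 ratio of 2.21 (interquartile range 1.87 to 2.87) and 27 were higher, so a group-wide interferon response may be present in that heart. A larger number of macrophages and monocytes at an unchanged interferon gene level per cell, as the whole cause, is argued against by 22 leukocyte markers. These were 20 of macrophages and monocytes and 2 of lymphocytes. Their median was 0.609 (0.431 to 1.04), and 21 were higher. Neutrophil markers were not in this set. Leukocytes with raised interferon genes per cell are not excluded by these markers. A smaller rise in such cells, infection and a reaction to surgery stay open and untested.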
